A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

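RNA-seq was carried out on 3 strains of the budding yeast Saccharomyces cerevisiae grown in synthetic medium lacking uracil with 20 g/l glucose. One strain carried wild-type ASK10 (WT), another lacked the gene (deletion), and the last carried an ASK10 allele with the M475R substitution (M475R). Per the labels' protocols, mRNA was isolated from total RNA and broken into fragments, which were copied to cDNA, joined to adapters, size-selected and amplified by PCR. Of the 6 samples in the series, 5 libraries had columns and were analysed: WT replicates 1 and 2, deletion replicate 2, and M475R replicates 1 and 2. Deletion replicate 1 was not analysed here. Columns were matched to samples by name, and groups came from the labels. Nothing in the labels says whether the replicates were separate cultures, so p-values measured only the spread between these libraries, which may be technical.

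BWA and Bowtie are named in the submitters' processing notes, without versions. The genome build, the annotation and the counting tool were not given in the sources used here, and gene identifiers carry the name of the laboratory strain CEN.PK113-7D. Per the file headers, the deposited pairwise tables give each gene an expression value per library, which the authors gave as an expected count that was not always whole. They also give an FPKM per library made by the authors, in which a gene at 0 was set to 0.001. The log2 ratio and the FDR of each pair in the deposited tables are the authors' own, and some deposited FDR values lie above 1, so that column was not used as a p-value. All genes in the authors' filtered lists had an FDR of 0.001 or below with an absolute log2 ratio of 1 or above. A pooled list of M475R against WT gives the authors' mean FPKM per strain, a log2 ratio and a probability of 0.8 or more. There were 7 full pairwise tables and 6 filtered lists. The filtered lists hold 20 further columns of per-sample values, which were not used; 0 of their values differed from the full tables. Likewise, 0 values of a library differed between the full tables.

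Expected counts were rounded to whole numbers and joined over 6032 listed genes. Identifiers were matched by locus tag to a reference gene table of assembly R64 (strain S288C), which was used only for names and for the order of neighbouring genes, since the authors' build may differ. Of the identifiers, 5515 matched, 5034 had a symbol other than the tag, and 517 did not match. Total expected counts were 102612 and 51576 for WT replicates 1 and 2, 117680 for the deletion, and 4155203 and 71228 for M475R replicates 1 and 2. M475R replicate 1 was therefore 35.3 to 80.6 times as deep as the other libraries. A level of 3 counts, taken as the floor of detection, corresponded to 32.3 and 63.8 CPM (counts scaled to the library total after TMM) in the WT libraries, 28.5 in the deletion, 0.8 in M475R replicate 1 and 45.2 in M475R replicate 2.

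Differential expression was tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test without robust estimation, with TMM scaling, filterByExpr on the 3 groups and 1 fit of all 5 libraries. Adjusted p-values in the text come from this test with Benjamini-Hochberg adjustment, and genes under 0.05 were called. The filter left 2909 genes. With 1 deletion library it needed a gene to reach its CPM limit in only 1 library, so low genes could enter through the strain where they were high. The common dispersion was 0.00101, a biological coefficient of variation (CV) of 3.2%, with 2 residual degrees of freedom. The prior degrees of freedom were infinite, so the quasi-likelihood spread was shared across genes and not estimated for each gene. The p-values and standard errors (SE) therefore carry little beyond counting error. The single deletion library was assumed to vary like the others. The median log2 fold change over tested genes was 0.012, 0.012 and -0.002 for M475R versus WT, M475R versus deletion and deletion versus WT. Count ratios are pooled counts over TMM-scaled library sizes, with exact 95% intervals from the conditional binomial test. Since M475R replicate 1 was far deeper, M475R ratios and intervals largely reflect that library, and replicate 2 adds little to them. Intervals and floors cover counting error only, since PCR copies are not independent molecules.

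Before averaging, libraries of a strain were compared by a chi-square test of their counts over genes with an expected count of at least 5. The WT pair gave a chi-square of 1.005 per degree of freedom (2001 genes, p = 0.436) and the M475R pair 1.025 (2876 genes, p = 0.168), whereas pairs of different strains gave 1.37 to 5.75. Both pairs thus differed by no more than the sampling noise, and each was counted as 1 sample. The fit keeps them apart, as fixed in the design, so its p-values compare these libraries and not strains or conditions.

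Before the data were examined, 26 gene lists were fixed, of which 25 had enough tested members. They were tested with camera (limma 3.58.1) on log CPM with a preset correlation of 0.01, again with an estimated correlation, and with fry. Each list's median pooled log2 ratio was also ranked among 10000 random lists of the same size matched on mean expression. Pooled log2 ratios had 20 CPM added to both sides, which makes them smaller than fitted log2 fold changes at low levels. They were also used for the chromosome segments and for the correlation and covariance of changes. The genes to be named were set by rule at the same time. They were ASK10, then the 10 largest rises and falls of each M475R comparison (6 each way for deletion versus WT) among called genes with a mean CPM of at least 10 and fully separated libraries. Up to 4 members per list with the smallest adjusted p followed, as did HSP26, HSP104, SSA1, SSA4, HSP82, HSC82, SIS1, YDJ1, GPD1, FPS1, RGC1 and URA3 whatever their values. Exceptions are named where they occur.

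The pipeline was tested on simulated counts in which 200 genes were changed by 1.5-fold, 2-fold or 4-fold. For M475R versus WT it recovered 22.4%, 43.3% and 62.1% of them by fold (2634 genes tested), for deletion versus WT 10.4%, 26.9% and 63.6% (2779 genes), and for M475R versus deletion 14.9%, 41.8% and 72.7% (2709 genes), all with the small spread estimated between libraries. With a simulated biological CV of 20%, the shares were 3%, 19.4% and 68.2% (2794 genes), 0%, 10.4% and 40.9% (2815 genes), and 0%, 10.4% and 60.6% (2921 genes) in the same order. To give the overlap of lists that share libraries, 100 sets of libraries with unchanged strains were also simulated, and lists of the observed sizes were taken from each by p-value. Camera called 5 of 5 shifted lists and 0 of 21 unshifted lists in the simulation. Simulated genes varied independently and their lists were drawn at random, so false calls among genes that vary together were not tested. Alternatives covered scaling (DESeq2 1.42.0 size factors, total counts), filters, DESeq2's Wald test, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a fit of only the groups compared, a 2-fold minimum, the replicate number as a block, and leaving out each library in turn. After the data were seen, a biological CV fixed at 10% or 20%, thinning of M475R replicate 1, removal of chromosome I and the left arm of chromosome XII, a contrast against both other strains, camera on negative binomial z-scores and 2 added gene lists were tried as well. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Genes with near-identical copies (TDH2 and TDH3, RPL8A and RPL8B and other ribosomal protein pairs, the Ty3 gene YGR109W-B) and overlapping genes such as YCR013C with PGK1 and YGR160W with NSR1 are uncertain, because the counting could split or share their reads and no use of strand is stated.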

Results

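Transcript levels were measured by RNA-seq in yeast strains with wild-type ASK10, without ASK10, or with the M475R allele, to ask how the allele and the loss of the gene alter expression, including that of chaperones. ASK10 encodes a regulator of the glycerol channel Fps1. The comparison used 2 WT libraries, 1 deletion library and 2 M475R libraries. The WT pair and the M475R pair each differed by no more than the sampling noise, so each pair stands for 1 sample of its strain. The fit still took the libraries separately, so its p-values compare libraries and not strains. Total expected counts ranged from 51576 to 117680 in 4 libraries and reached 4155203 in M475R replicate 1.

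ASK10 (YGR097W) itself was read 5 and 7 times in the WT libraries, 0 times in the deletion library, and 567 and 4 times in M475R replicates 1 and 2. These counts correspond to 53.8 (95% exact Poisson interval 17.5 to 126) and 149 (59.8 to 307) CPM in WT, and 148 (136 to 161) and 60.2 (16.4 to 154) CPM in M475R. The pooled ASK10 level was 3-fold the deletion library's floor of 3 counts in WT and 5.14-fold that floor in M475R. These ratios to the floor are not lower limits. The exact 95% lower limit of the ratio of M475R to the deletion was 4.17. Taken singly, WT replicate 1 lay 1.89-fold and M475R replicate 2 lay 2.11-fold above that floor. ASK10 was called lower in the deletion than in WT (adjusted p = 0.0397), a call lost without WT replicate 2 (0.372) or without M475R replicate 1 (0.56). Its call above the deletion in M475R (adjusted p = 1.74e-06) was likewise lost without M475R replicate 1 (0.461). M475R and WT did not differ detectably in ASK10 at this depth (ratio 1.71, 95% interval 0.972 to 3.33, two-sided exact binomial p = 0.0689).

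**Figure D1:**
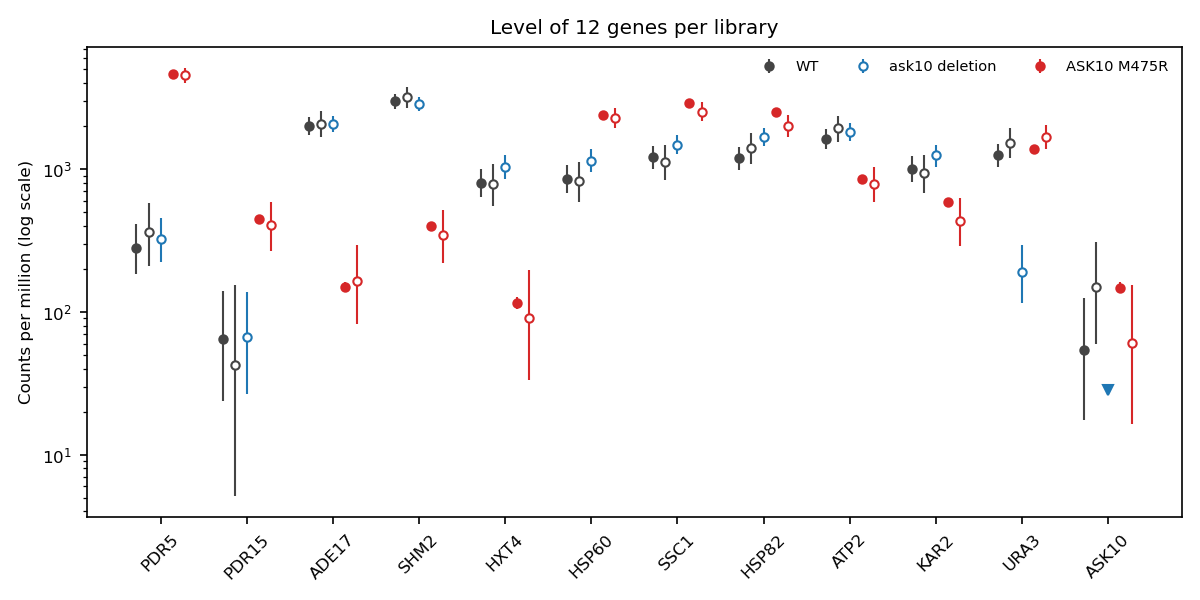
Levels of 12 genes in CPM (log axis) in each library of WT, deletion and M475R, with filled points for replicate 1, open points for replicate 2, bars for exact 95% Poisson intervals, and a triangle at the level of 3 counts where the count was 0. PDR5 lay near 4620 CPM in M475R replicate 1 and between 280 and 361 CPM in the WT and deletion libraries, and ASK10 had no count in the deletion library.

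In the comparison of M475R with WT, the largest well-measured rise was that of PDR5, which encodes a plasma membrane drug efflux pump. PDR5 was 15-fold higher in M475R (95% interval 11.2 to 20.8, log2 fold change 3.90 ± 0.15 SE, adjusted p = 7.81e-139), and PDR15, a related transporter gene, was 7.81-fold higher (3.95 to 18.1). The deepest fall was that of ADE17, an enzyme of purine synthesis, at 0.0734 times the WT level (0.0636 to 0.0848, log2 fold change -3.77 ± 0.13 SE, adjusted p = 1.79e-161). The purine synthesis genes ADE1 (ratio 0.186), ADE2 (0.191) and ADE57 (0.219) fell as well, as did SHM2 (0.13, 95% interval 0.117 to 0.145) and MTD1 (0.148), which act in one-carbon metabolism. The glucose transporter gene HXT4 dropped to 0.144 times WT (0.117 to 0.178), and the uncharacterised gene YOR387C to 0.0928 times (0.0696 to 0.125).

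Of 2909 genes tested, 246 were higher and 294 lower in M475R than in WT, and 519 of these 540 had both M475R libraries beyond both WT libraries. Selection of called genes itself favours such separation, and the 33.3% that chance gives holds for unselected genes. At least 2-fold, 158 were higher and 69 lower. Several of the other largest rises rested on 1 to 3 WT counts and are given as ratios with their counting intervals. The mitochondrial ribosomal protein gene MRPL38 stood at 16.5 (2.95 to 654), SDH5, an assembly factor of succinate dehydrogenase, at 14.8 (2.65 to 588), the hexokinase gene HXK1 at 12 (2.14 to 476) and the trehalose synthase subunit gene TSL1 at 8.89 (3.03 to 43.2). RSM26 (7.6, 2.59 to 36.9), FMP10 (7.09, 2.42 to 34.5) and LSB6 (5.84, 1.6 to 48.4) completed the rises apart from YGR109W-B, a multi-copy Ty3 gene with 0 WT counts, which was at least 5.82-fold higher against the WT floor of 3 pooled counts. VEL1 (ratio 0.208, 0.143 to 0.311) and the thiamine transporter gene THI7 (0.237, 0.17 to 0.34) completed the falls.

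Leaving out WT replicate 1 left 74 genes higher and 115 lower, and leaving out M475R replicate 1 left 77 and 99. Of the 20 genes named for the size of their change, at least 6 lost their call when 1 library was left out. Genes that the filter dropped from such a fit were not scored there, so further calls may depend on 1 library. HXK1 (highest adjusted p 0.511), FMP10 (0.125) and VEL1 (0.378) did so without either WT replicate 1 or M475R replicate 1, TSL1 without M475R replicate 1 (0.0982), THI7 without WT replicate 1 (0.187) and LSB6 without WT replicate 2 (0.208). With a biological CV fixed at 20%, 11 genes were higher and 19 lower.

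Some chaperone genes of the cytosol and of mitochondria were higher in M475R than in WT, while those of TRiC and prefoldin did not pass (smallest adjusted p = 0.197, CCT6). Of 20 tested members of the list of cytosolic chaperones and heat shock genes, 6 rose and 14 did not pass (8 rose when adjusted over the list alone). The Hsp90 gene HSP82 was 1.99-fold higher (95% interval 1.72 to 2.33), the disaggregase gene HSP104 1.91-fold higher (1.41 to 2.65), and the small heat shock gene HSP26 3.49-fold higher (1.59 to 9.56). The list was called higher by camera (median log2 fold change 0.42, adjusted p = 0.00397), with adjusted p = 0.237 with an estimated correlation. Among 10 mitochondrial chaperone genes, 6 rose (also 6 adjusted over the list alone), led by HSP60 at 2.83-fold (2.36 to 3.42), SSC1 at 2.44-fold (2.09 to 2.86) and HSP10 at 2.48-fold (1.76 to 3.61). This list had a median of 0.88 (adjusted p = 0.00308, and adjusted p = 0.237 with an estimated correlation), and 0 of 10000 random lists were as high. SIS1, an Hsp40 gene, rose 1.7-fold (1.21 to 2.47, adjusted p = 0.00819), whereas SSA4 (ratio 1.37, adjusted p = 0.546) and YDJ1 (1.32, adjusted p = 0.0822) did not pass. HSP26 lost its call without WT replicate 1 (adjusted p = 0.228) or M475R replicate 1, and SIS1 without WT replicate 1 (0.149) or WT replicate 2. SSA1 and HSC82 were not analysed here. HSC82 also encodes Hsp90, so HSP82 counts in every comparison may include reads from it.

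The lists of general stress, trehalose and glycolytic genes were also higher in M475R than in WT. These lists share members and are not separate results. TPS1, TPS2 and TSL1 are in both the stress and trehalose lists, and HXK1 and GLK1 in both the stress and glycolysis lists. HSP26 is in the stress list and the cytosolic chaperone list. In M475R versus deletion, the stress and trehalose lists had medians of 0.45 and 0.47, and neither was called. In deletion versus WT, their medians were 1.07 and 0.49, and both were called higher. The rises of M475R and of the deletion use the same WT sample. A change in both strains and a shift of that sample cannot be told apart. Of 34 measured targets of the stress regulators Msn2 and Msn4, 12 were tested, and 9 of these rose (10 adjusted over the list alone). Among them were YGP1 (4.47-fold, 2.55 to 8.67), GLK1 (3.37-fold, 2.03 to 6.03) and GRE3 (4.28-fold, 2.16 to 9.94). The tested members had a median of 1.55 (camera adjusted p = 7.75e-06, and adjusted p = 0.237 with an estimated correlation). The filter could admit a member through the strain where it was high. In WT, HXK1 stood at 7.15, TSL1 at 21.4 and HSP26 at 42.9 CPM. The share that rose, the median and the test may thus overstate the change of the whole list, as may those of the trehalose list. In the list of 18 trehalose and glycogen genes, 7 were tested and 4 of these rose (5 adjusted over the list alone), with TPS1 at 2.55-fold (1.56 to 4.48) and TPS2 at 2.31-fold. Its median was 1.16 (adjusted p = 0.0034, and adjusted p = 0.237 with an estimated correlation), and without M475R replicate 1 the calls of TPS1 (adjusted p = 0.45) and TPS2 (0.0832) were lost. Among 18 genes of glycolysis and ethanol formation, 14 rose and 1 fell (15 and 1 adjusted over the list alone). TDH3 rose 1.65-fold (1.58 to 1.73) and PGK1 1.77-fold (1.66 to 1.9), while ADH4 fell to 0.425 times WT (0.384 to 0.471), and the list had a median of 0.43 (adjusted p = 0.0022, and adjusted p = 0.237 with an estimated correlation). Part of the TDH3 count may belong to its near-identical copy TDH2.

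The lists of glycerol metabolism genes and of proteasome genes were also higher, yet both calls were lost without WT replicate 1 (adjusted p = 0.0857 and 0.0711). Of 11 tested genes of glycerol metabolism and osmotic stress, 4 rose (4 adjusted over the list alone), including the glycerol-3-phosphatase gene GPP2 (3.17-fold, 1.84 to 5.96) and the glycerol-3-phosphate dehydrogenase gene GPD1 (2.15-fold, 1.52 to 3.16, adjusted p = 0.333 without WT replicate 1). The list median was 0.51 (adjusted p = 0.0134, and adjusted p = 0.252 with an estimated correlation). FPS1 (ratio 0.999, adjusted p = 0.999) and its regulator RGC1 (1.61, adjusted p = 0.259) did not pass. Among 35 proteasome genes, 5 rose (5 adjusted over the list alone), with RPN3 at 1.71-fold and RPN8 at 1.97-fold, and a median of 0.34 (adjusted p = 0.00351, and adjusted p = 0.237 with an estimated correlation). RPN3 (adjusted p = 0.165) and RPN8 (0.685) lost their calls without WT replicate 1.

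Lists of genes of respiration, translation and amino acid synthesis were lower in M475R than in WT. Of 26 tested genes of the respiratory chain and ATP synthase, 18 fell and 8 did not pass (19 fell adjusted over the list alone), including the ATP synthase subunit genes ATP2 (0.493 times WT, 0.433 to 0.564), ATP3 (0.452) and ATP5 (0.455). The list had a median of -1.04 (adjusted p = 1.43e-10, and adjusted p = 0.237 with an estimated correlation). Among 127 cytosolic ribosomal protein genes, 96 fell and 31 did not pass (105 fell adjusted over the list alone), with RPL3 at 0.728 (0.684 to 0.775), RPS31 at 0.633 and RPL9A at 0.503 (0.444 to 0.573), the last with a near-identical copy. That list had a median of -0.46 (adjusted p = 1.03e-15, and adjusted p = 0.237 with an estimated correlation). Of 63 ribosome biogenesis genes, 24 fell (33 adjusted over the list alone), for example NSR1 at 0.573, with a median of -0.58 (adjusted p = 2.54e-10, and adjusted p = 0.237 with an estimated correlation). Among 44 amino acid biosynthesis genes controlled by Gcn4, 18 fell and 1 rose (19 and 1 adjusted over the list alone), including BAT1 at 0.418 (0.354 to 0.495) and ILV5 at 0.646, with a median of -0.21 (adjusted p = 0.00308, and adjusted p = 0.237 with an estimated correlation). For the respiratory, ribosomal protein and ribosome biogenesis lists, 0 of 10000 random lists had as low a median, while 925 did for the Gcn4 list.

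The other fixed lists were not called for M475R versus WT, although single members passed. In the TCA and glyoxylate list 6 of 20 rose and 1 fell, with ACO1 at 2.88-fold (2.42 to 3.44) and IDH1 at 3.16-fold (2.2 to 4.73), while the list itself gave adjusted p = 0.185. Of 20 oxidative stress genes 5 rose, including AHP1 at 2.17-fold (list adjusted p = 0.0908, but 0.0477 without WT replicate 1, 0.0129 without the deletion library, 0.0418 without M475R replicate 1 and 0.0146 without M475R replicate 2). Of 13 genes of ER folding and the unfolded protein response 3 fell (list adjusted p = 0.096), with the ER Hsp70 gene KAR2 at 0.596 (0.501 to 0.713, adjusted p = 0.0687 without WT replicate 1). Cell wall genes divided into 3 higher and 1 lower of 24 (list adjusted p = 0.547), with CWP1 at 5.62-fold on 3 WT counts (1.91 to 27.3). Hexose transport gave 3 higher and 1 lower of 6 (0.286), the pentose phosphate list 2 higher and 1 lower of 8 (0.619), and sulfur assimilation 1 higher and 3 lower of 14 (0.585), with MET6 at 0.663. Ergosterol synthesis had 3 higher of 24 (0.307), the iron regulon 2 lower of 9 (0.394), phosphate starvation 1 lower of 7 (0.547) and the hypoxic list 1 lower of 3 (0.547). Auxotrophic marker genes had 2 lower of 7 (0.272, but 0.0175 without M475R replicate 2), one of them ADE2. In the list of TRiC and prefoldin genes the smallest adjusted p was that of CCT6 (ratio 1.25, adjusted p = 0.197; list 0.585), and in the mating list that of STE2 (log2 fold change -0.36, adjusted p = 0.19; list 0.11). Adjusted over the list alone, these counts were equal except in the cell wall list (2 higher and 1 lower) and the hexose list (4 higher and 1 lower). The median, mean or test of the pentose phosphate, sulfur, phosphate and hypoxic lists differed in sign. The sporulation list had 0 tested members.

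**Figure D2:**
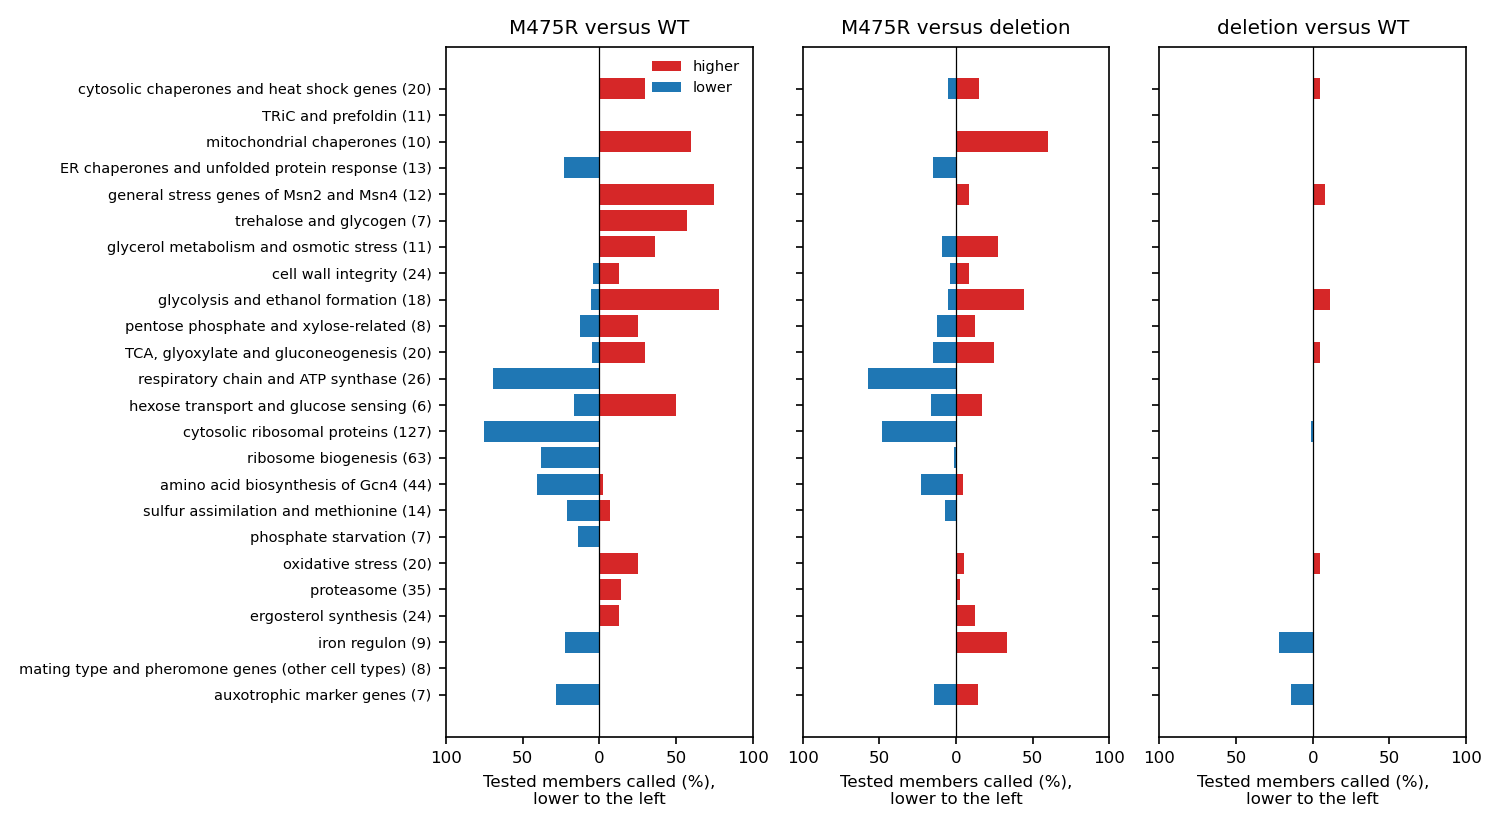
Percent of the tested members of each gene list called higher (right of 0) or lower (left of 0), with the number tested, for M475R versus WT, M475R versus deletion and deletion versus WT. Of 26 respiratory genes, 18 were called lower in M475R than in WT and 15 lower than in the deletion. Of 127 ribosomal protein genes, 96 and 61 were called lower, and 1 was called higher than in the deletion.

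M475R was also compared with the deletion strain, which sets the allele against the loss of the gene. PDR5 was 14.3-fold higher in M475R (95% interval 10.2 to 20.6, log2 fold change 3.83 ± 0.17 SE, adjusted p = 7.53e-103), and PDR15 was 6.7-fold higher (3.25 to 16.7). ADE17 stood at 0.0723 times the deletion level (0.0618 to 0.0849, log2 fold change -3.79 ± 0.15 SE, adjusted p = 6.53e-129), SHM2 at 0.139 (0.123 to 0.158), MTD1 at 0.193, ADE4 at 0.221 (0.18 to 0.274) and HXT4 at 0.111 (0.0898 to 0.138). ADE1 fell to 0.108 (0.0908 to 0.128) and SDH2, a succinate dehydrogenase subunit gene, to 0.224 (0.169 to 0.302). ADE1 lies at the right end of chromosome I and SDH2 at the left end of chromosome XII. Most tested genes there lay above WT in the deletion library, and 3 of 14 and 5 of 21 were called higher. The thiamine genes THI7 (0.11, 0.0833 to 0.146) and THI20 (0.235, 0.154 to 0.375) and YOR387C (0.187, 0.122 to 0.297) were lower too. URA3, the uracil synthesis gene used as a selection marker in yeast, was 7.26-fold higher in M475R (4.7 to 11.9), and RPL8A, which has the near-identical copy RPL8B, 6.99-fold higher (4.3 to 12.2). CWP1 (12.7, 2.26 to 501), NAR1 (9.32, 1.66 to 369), AIM36 (7.03, 1.94 to 58.2) and MRPL31 (6.59, 2.25 to 32) rested on 1 to 3 deletion counts. YGR109W-B stood at 4.37-fold the floor (exact 95% lower limit of the ratio 3.54).

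Altogether 119 genes were higher and 180 lower in M475R than in the deletion, and 297 of these 299 had both M475R libraries on the same side, which the selection of called genes favours (66.7% by chance for unselected genes). Scaling by total counts gave 156 higher and 145 lower. Without M475R replicate 1, 41 were higher and 64 lower, and the calls of ASK10 (adjusted p = 0.461), MRPL31 (0.168), YOR387C (0.0778) and THI20 (0.0512) were lost. Genes that the filter dropped from a fit with 1 library left out were not scored there. With a biological CV fixed at 20%, 11 were higher and 26 lower.

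Some mitochondrial chaperone genes were higher, and some respiratory and ribosomal protein genes lower, in M475R than in the deletion. Of 10 mitochondrial chaperone genes 6 rose (6 adjusted over the list alone), with HSP60 at 2.09-fold (1.75 to 2.52), SSC1 at 1.93-fold (1.65 to 2.28) and HSP10 at 3.23-fold (2.06 to 5.38), and a median of 0.94 (adjusted p = 0.000181, and adjusted p = 0.379 with an estimated correlation). Of 26 respiratory genes 15 fell (17 adjusted over the list alone), with QCR2 at 0.292 (0.233 to 0.369), ATP1 at 0.412 (0.345 to 0.496) and ATP2 at 0.469, and a median of -1.08 (adjusted p = 7.11e-13, and adjusted p = 0.379 with an estimated correlation). Of 127 ribosomal protein genes 61 fell and 1 rose (85 and 2 adjusted over the list alone), with RPL9A at 0.507, RPL8B at 0.376 and RPL8A as the gene that rose. Their median was -0.42 (adjusted p = 1.39e-12, and adjusted p = 0.379 with an estimated correlation). RPL8B lies at the left end of chromosome XII, as does SDH2. ER folding genes had 2 lower of 13 (3 adjusted over the list alone), with KAR2 at 0.471 (0.395 to 0.567), a median of -0.58 and adjusted p = 0.017, and adjusted p = 0.379 with an estimated correlation. Ribosome biogenesis genes, with 1 of 63 lower (NOP56, ratio 0.702) and a median of -0.24, were called lower at adjusted p = 0.0266, with adjusted p = 0.379 with an estimated correlation. Without M475R replicate 1 the ER list (adjusted p = 0.103), the ribosome biogenesis list (0.308) and NOP56 (0.476) were not called, and NOP56 was also lost without M475R replicate 2. The proteasome list was called higher with a median of 0.27 (adjusted p = 0.0149, and adjusted p = 0.379 with an estimated correlation), although 1 of its 35 genes, PRE3, passed (2.07-fold, adjusted p = 0.53 without M475R replicate 1).

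Among cytosolic chaperones 3 of 20 rose and 1 fell (4 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.215). STI1 was 2.06-fold higher (1.51 to 2.88) and HSP82 1.49-fold higher (1.28 to 1.74). HSP104 stood at 0.664 times the deletion level (0.54 to 0.826) and lies at the left end of chromosome XII, as does FPS1 (0.46, 0.32 to 0.684). Calls of STI1 (adjusted p = 0.0935), HSP82 (0.553), HSP104 (0.323) and FPS1 (0.575) were lost without M475R replicate 1. HSP26 (ratio 1.75, adjusted p = 0.292), SSA4 (2.26, 0.212), SIS1 (1.28, 0.441), YDJ1 (1.19, 0.501), GPD1 (1.52, 0.0885) and RGC1 (0.953, 0.951) did not pass. Glycolysis had 8 higher and 1 lower of 18 (12 and 1 adjusted over the list alone, list adjusted p = 0.0943), with TDH3 at 1.43-fold, GPM1 at 1.54-fold and PGK1 at 1.49-fold. The TCA list divided into 5 higher and 3 lower of 20, with ACO1 at 3.19-fold (2.59 to 3.97) and IDH1 at 2.09-fold. Among Gcn4 targets 10 fell and 2 rose of 44 (11 and 4 adjusted over the list alone, list adjusted p = 0.101), with BAT1 at 0.377 (0.315 to 0.454), HIS1 at 0.375 and HIS4 at 0.442. Glycerol genes gave 3 higher and 1 lower of 11 (0.0943), iron genes 3 higher of 9 (0.096, but 0.0125 without M475R replicate 2), ergosterol genes 3 higher of 24 (0.113), cell wall genes 2 higher and 1 lower of 24 (0.523), and Msn2 and Msn4 targets 1 higher of 12 (0.164). Pentose phosphate, hexose transport and marker gene lists each had 1 higher and 1 lower gene, oxidative stress 1 higher and sulfur 1 lower. Adjusted over the list alone, glycerol genes gave 4 higher and 1 lower, iron genes 5 and 1, pentose phosphate genes 1 and 3, and hexose transport genes 2 and 1. In that adjustment the single calls of the oxidative stress, ribosome biogenesis and proteasome lists did not pass, and counts of the TCA, ergosterol, cell wall, Msn2 and Msn4, marker and sulfur lists were equal to those over all genes. The median, mean or test of the TRiC, cell wall, pentose phosphate, TCA, hexose, mating and marker lists differed in sign. The smallest adjusted p was 0.127 in the trehalose list (TPS2), 0.19 in the phosphate list (VTC3), 0.0511 among TRiC genes (CCT4), 0.309 in the hypoxic list (ROX1) and 0.207 in the mating list (SST2).

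Between deletion and WT, 14 genes were called higher and 6 lower in the deletion, at a depth where 26.9% of simulated 2-fold changes were recovered. YBT1, a vacuolar transporter gene, was 3.9-fold higher (95% interval 2.49 to 6.27, log2 fold change 1.96 ± 0.30 SE, adjusted p = 3.27e-08), SDH2 3.18-fold (1.92 to 5.43), HSP104 2.88-fold (1.99 to 4.23), VPS13 2.86-fold (1.65 to 5.14) and RFA1 2.8-fold (1.61 to 5.03). HXK1 stood at 15 counts against 1 (ratio 20, 3.07 to 841). URA3 dropped to 0.142 times WT (0.0846 to 0.225, log2 fold change -2.82 ± 0.28 SE, adjusted p = 1.94e-20), from 116 and 72 counts in the WT libraries to 20. RPL8A, whose reads could be split with RPL8B, stood at 0.109 (0.0609 to 0.181), while RPL8B was 1.75-fold higher (1.56 to 1.98), and their sum was 1.27-fold higher (1.14 to 1.42). The iron uptake genes FET3 (0.369, 0.222 to 0.591) and FRE1 (0.102 on 2 deletion counts, 0.0118 to 0.409) were lower, as were ZPS1 (0.683, 0.578 to 0.805) and ASK10 itself.

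Of the 14 higher genes, 8 lie at 2 chromosome ends that hold 35 of the 2909 tested genes. At the right end of chromosome I, 12 of 14 tested genes lay above WT in the deletion library with a median pooled log2 ratio of 0.77. At the left end of chromosome XII, 20 of 21 did so with a median of 0.80. The same genes had medians of -0.04 and -0.06 in M475R versus WT. YBT1, SDH2, HSP104, VPS13 and RPL8B belong to the segment on XII, and RFA1, EFB1 and ADE1 to that on I. Both segments were found from these values, so their medians describe the genes and test nothing.

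**Figure D3:**
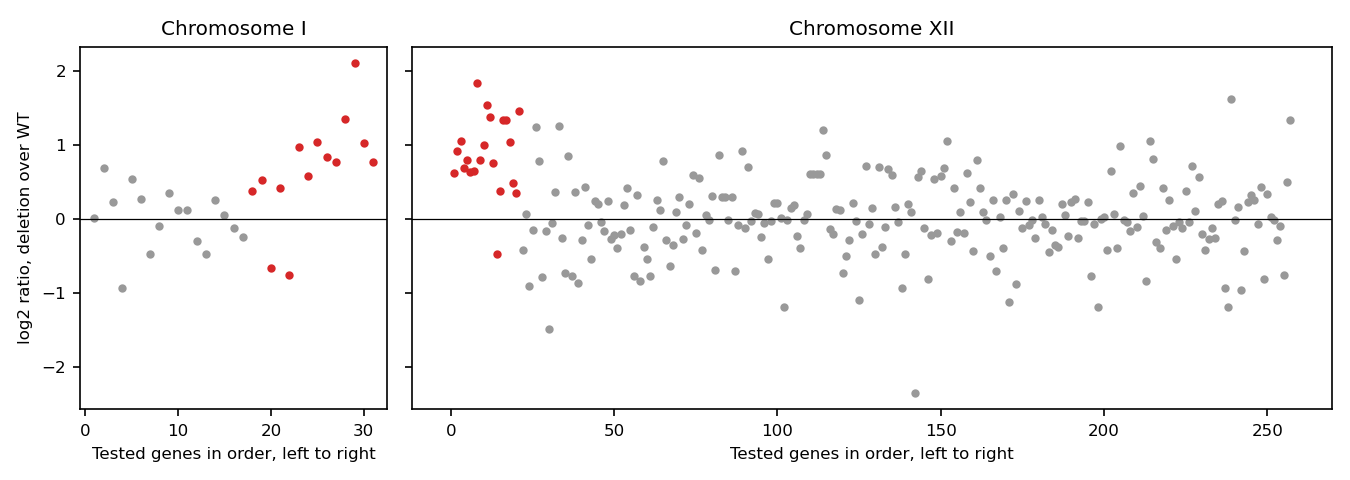
Pooled log2 ratio of deletion to WT (20 CPM added to both sides) for tested genes in their order along chromosomes I and XII, with the 2 end segments in red. Red points on the right end of I and the left end of XII have medians of 0.77 and 0.80, and medians of the chromosome arms other than both arms of I and the left arm of XII lie between -0.1 and 0.07.

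General stress genes as a list were higher in the deletion than in WT, with 1 of 12 called over all genes and 6 adjusted over the list alone (median 1.07, adjusted p = 1.24e-05, and adjusted p = 0.558 with an estimated correlation). Trehalose genes, some of them also in the stress list, followed with a median of 0.49 and 2 of 7 higher adjusted over the list alone. Camera gave that list adjusted p = 0.0058, and adjusted p = 0.558 with an estimated correlation, and the call was lost without WT replicate 1. Ribosome biogenesis genes were lower as a list (median -0.35, adjusted p = 1.24e-05, and adjusted p = 0.558 with an estimated correlation), although none of the 63 passed singly in either adjustment, NSR1 (ratio 0.626, 0.465 to 0.835, adjusted p = 0.168) included. The iron regulon was lower with 2 of 9 called and 3 adjusted over the list alone (median -0.70, adjusted p = 0.0123, and adjusted p = 0.558 with an estimated correlation). The other 21 tested lists were not called, and among them glycolysis had 2 higher of 18 (7 adjusted over the list alone), with ENO1 at 1.18-fold, and oxidative stress 1 of 20 (2 adjusted over the list alone), with AHP1 at 1.65-fold (1.3 to 2.11). Adjusted over the list alone, the TCA list had 2 higher, the respiratory list 1 higher, the hypoxic list 1 lower and the marker list 2 lower, against 1 higher, none, none and 1 lower over all genes. The ribosomal protein list had 1 higher and 1 lower gene (RPL8B and RPL8A) and the cytosolic chaperone list 1 higher (HSP104) in either adjustment. The median, mean or test of the TRiC and cell wall lists differed in sign. For the stress and trehalose lists, the filter and the single WT sample limit the reading as they do in M475R versus WT. HSP26 (ratio 2, adjusted p = 0.77), HSP82 (1.34, 0.352), SSA4 (0.605), SIS1 (1.33), YDJ1 (1.11), GPD1 (1.41), FPS1 (2.17, 0.289) and RGC1 (1.69) did not pass. Leaving out WT replicate 1 left 4 genes higher, with the calls of HXK1 (adjusted p = 0.811), SDH2 (0.441), VPS13 (0.311), RFA1 (0.627), FRE1 (0.311), ENO1 (0.547) and AHP1 (0.301) lost, and leaving out WT replicate 2 left 9 higher, with HXK1, VPS13, FRE1, ENO1, AHP1, ASK10 (0.372), FET3 (0.052) and ZPS1 (0.284) lost. ENO1 and AHP1 were also lost without M475R replicate 2, and ENO1, HXK1 and ASK10 without M475R replicate 1.

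The M475R changes against WT and against the deletion shared 78 higher and 139 lower genes, where independent lists of these sizes would share 10.1 and 18.2. Both comparisons use the same M475R libraries, and lists of these sizes from simulated unchanged strains shared 14.2 and 22.8 genes on average (at most 23 and 31 in 100 simulations). M475R and the deletion, each against the same WT libraries, shared 5 higher and 4 lower genes, where independent lists would share 1.2 and 0.6 but simulated unchanged strains shared 11.1 and 4.4. A further 4 genes (ADE1, RPL8B, THI7 and INO1, the last chosen after its values were seen) were lower in M475R and higher in the deletion than in WT. Independent lists would share 1.4. The simulations of unchanged strains gave 0, but there the noise of the shared WT libraries moves both changes the same way. That 0 is thus no measure of chance for opposite changes. ADE1 and RPL8B lie in the chromosome ends where most tested genes lay above WT in the deletion library. Across the 2909 genes, which are not independent replicates, the log2 ratios of deletion and of M475R over WT had a Pearson r of 0.47 and a Spearman rho of 0.5. Simulated unchanged strains against these WT libraries gave an r of 0.63. That simulation lacked the M475R changes, whose spread lowers r, so r of 0.47 and 0.63 are not comparable. The simulated overlaps of M475R and the deletion against WT share this limit. The covariance of these log2 ratios was 0.135, against 0.084 in the simulation, a difference of 0.051. With WT replicate 1 as the reference of one change and WT replicate 2 of the other, r was 0.12 or 0.11 and the covariance 0.049 or 0.047, against 0 in the simulation.

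The authors' deposited table of M475R against WT lists 88 genes, 65 higher and 23 lower, of which 21 and 16 were called in the same direction here and 45 were not tested. In the authors' deposited table the mean FPKM of PDR5 was 64.6 in WT and 942 in M475R (log2 ratio 3.87), that of ADE17 was 1080 and 84.3 (-3.67), and that of SHM2 was 2060 and 253 (-3.03). The authors' deposited table of M475R replicate 1 against the deletion lists 85 genes (28 higher, 57 lower), and that of M475R replicate 2 lists 31 (10 and 21). Against WT replicates 1 and 2, the authors' deposited tables list 4 and 2 genes for the deletion.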

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

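The fits with a biological CV fixed by hand, the thinned library, the removal of chromosome I and the left arm of XII, the contrast against both other strains and camera on negative binomial z-scores were tests chosen only after the results were seen, and the other settings were planned. Named genes called in a comparison (177 pairs of gene and comparison) kept direction and call in 2363 settings, lost the call with the same direction in 909 and reversed in 0. Where the filter or DESeq2 left a gene without an adjusted p in a setting, that setting was not counted for it. The 20 pairs that were not called stayed so in 345, passed in 6 and changed sign in 8. When 1 library was left out, ASK10 in M475R versus WT gave log2 fold changes from -0.53 to 1.44 (-0.01 without WT replicate 1), URA3 in M475R versus WT from -0.11 to 0.36, and RGC1 in M475R versus deletion from -0.06 to 0.22. RGC1 in M475R versus deletion also changed sign with limma on FPKM (0.1 with either pseudocount) and with M475R replicate 1 thinned (0.04), and the cause was not tested.

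Counts of called genes moved with the tool, the spread assumed, the depth, the libraries left out and, for deletion versus WT, the groups fitted and the chromosome regions kept. In M475R versus WT, against 246 higher and 294 lower genes, a 2-fold minimum gave 158 and 69, DESeq2 35 and 97, limma on log2(FPKM + 1) 44 and 45 and on log2(FPKM + 0.1) 40 and 42, a CV of 10% gave 119 and 108, a CV of 20% gave 11 and 19, and thinning gave 108 and 168. Leaving out 1 library gave 74 to 251 higher and 99 to 267 lower, lowest without WT replicate 1 for the higher genes and without M475R replicate 1 for the lower ones. In M475R versus deletion, against 119 and 180, DESeq2 gave 19 and 48, limma on FPKM 8 and 9 or 5 and 8 by pseudocount, a CV of 10% gave 45 and 83, a CV of 20% gave 11 and 26, thinning gave 61 and 108, a 2-fold minimum left 72 lower, limma-voom gave 360 lower, and leaving out 1 library gave 41 to 127 and 64 to 189. In deletion versus WT, against 14 and 6, a 2-fold minimum left 7 higher, DESeq2 gave 2 and 2, the fit of only these groups 0 and 2, limma on FPKM 0 and 2 with either pseudocount, a CV of 10% gave 5 and 3, a CV of 20% gave 0 and 2, removal of both chromosome regions left 4 higher, and leaving out 1 library gave 4 to 11 and 4 to 6. Beside the 0 higher genes, those with an unadjusted p under 0.05 numbered 84 with edgeR on only these groups, 95 and 90 with limma on FPKM at pseudocounts 1 and 0.1, and 59 with edgeR at a CV of 20%, and limma-voom called 20. The smaller counts with fewer libraries, fewer counts or a larger fixed spread follow from those constructions, and for the other tools the cause was not tested.

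Deviations of same-numbered WT and M475R libraries had an r of -0.03 across genes over 2 pairs. Since both pairs differed by no more than counting noise, that r cannot show whether replicate numbers pair the libraries. The replicate block changed the sign of RGC1 in M475R versus deletion (0.38 against -0.07), and gave 51 higher and 105 lower genes in M475R versus deletion and 6 higher in deletion versus WT. Under this block the ER list (adjusted p = 0.0828) and the ribosome biogenesis list (0.118) in M475R versus deletion and the iron list in deletion versus WT (0.112) were not called, and it ended no other list call. With an estimated correlation, camera called 0 of the 11, 6 and 4 lists called in M475R versus WT, M475R versus deletion and deletion versus WT. Unadjusted, 3, 2 and 1 lists passed in that test, and fry called 16, 7 and 0. Camera on z-scores added the TCA (adjusted p = 0.0168) and oxidative stress lists (0.0393) in M475R versus WT, the glycolysis (6.43e-07) and Gcn4 lists (0.0271) in M475R versus deletion, and the glycolysis, TCA, ribosomal protein, oxidative stress and marker lists in deletion versus WT (9 called in all), and it ended the call of ribosome biogenesis in M475R versus deletion (adjusted p = 0.0656). Removal of both chromosome regions added calls for the glycerol (adjusted p = 0.0212) and iron lists (0.0152) in M475R versus deletion. The correlation of the changes against WT moved from 0.47 to 0.12 and 0.11 with the WT libraries split, which removes their shared noise. Calls shared by every pair in the authors' deposited tables numbered 17 for M475R versus WT (88 in the pooled list), 30 for M475R versus deletion (85 in the longer list) and 2 for deletion versus WT (4 in the longer list). Depth limits the comparisons through the WT and deletion libraries, where 3 counts stand for 28.5 to 63.8 CPM.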

Other observations

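The tests of replicate likeness, of extra copies, of noise in WT and of depth were chosen only after the result was seen, while the 2 tests on list members not yet seen were set before. Members were listed for purine and one-carbon synthesis and for drug resistance targets of the regulators Pdr1 and Pdr3 after the changes of ADE17 and PDR5 had been seen. Of 31 tested purine and one-carbon genes, 20 were lower in M475R than in WT (median log2 fold change -1.10), and 19 were lower in M475R than in the deletion (median -0.98). The same list had a median of -0.07 in deletion versus WT. Of 16 tested Pdr1 and Pdr3 targets, 9 were higher in M475R than in WT (median 1.14), and 7 were higher and 1 lower than in the deletion (median 1.12). Their median in deletion versus WT was 0.17. Because members whose change had been seen are among them, these counts and medians describe both lists and do not test them.

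ADE17 and other purine genes already seen were lower, and PDR5 and PDR15 higher, in M475R than in both other strains. M475R replicate 2 alone gave a purine median log2 fold change of -1.13 over 30 tested genes and a drug list median of 1.53. In the same fit PDR5 stood at 3.92 and ADE17 at -3.57. Genes named for size were chosen with both M475R libraries beyond the WT libraries, so their direction in replicate 2 was fixed by that choice. Their sizes were not, and these argue against the great depth of M475R replicate 1 as the source of changes this large. Both medians include members already seen. A response of the whole Pdr1 and Pdr3 list may be involved, as 12 members not yet seen had a median of 0.96 with 6 higher (camera p = 0.0454, but p = 0.169 with an estimated correlation). These 12 include ATR1 and FLR1, which had been tested within the oxidative stress list. The filter could also admit a member through M475R alone, which can raise the median. Likewise, the unseen purine members include ADE3 of the Gcn4 list and LPD1 of the TCA list. For the whole purine list the 17 unseen members gave -0.24 with 7 lower (camera p = 0.000432, and p = 0.063 with an estimated correlation), a median between the bounds set beforehand, so a decrease of the whole list stays open. An effect of the allele itself is untested, and no label names a batch within which the strains could be compared.

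Both pairs of replicate libraries differed by no more than counting noise, with a chi-square of at most 1.025 per degree of freedom. That value is consistent with 1 RNA or library per strain sequenced more than once. Separate cultures with a biological CV of 10% or more are argued against, because the upper 95% limit of the CV within a pair was at most 4.8%, and a CV of 10% was detected in 100 of 100 simulated pairs of each strain. Cultures varying by less than that limit remain possible, and a CV of 5% was detected in 75 of 100 simulated WT pairs and 99 of 100 M475R pairs.

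Most tested genes at the right end of chromosome I (12 of 14) and the left end of chromosome XII (20 of 21) lay above WT in the deletion library. Of these, 3 and 5 were called higher. Counting noise of the shallow WT libraries is argued against, since the deletion over M475R replicate 1, a comparison without WT, still gave medians of 0.74 and 0.91. Extra copies of both segments in the deletion strain may be an explanation, but genes there that were too low to be tested gave ratios of 1.36 (95% interval 1 to 1.85) and 1.57 (0.876 to 2.84), too few counts to decide. With 1 deletion library, a property of the strain and one of that library cannot be told apart for these genes.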
